A study of Mus musculus with 20 samples.

How the data were processed

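RNA-seq libraries of 3T3-L1 cells carrying a hairpin against Tcf7l2 or a scrambled hairpin were taken from the deposited tables, 2 per hairpin at each of days 0, 2, 4, 6 and 8, which gives 20 libraries in 10 groups. Each of the 5 deposited tables holds 1 day with 33581 genes. Per the labels, libraries were made with the TruSeq kit, and cells were a puromycin-selected mixed population. Per the submitters' processing notes, reads were aligned to mm9 with TopHat2 2.0.13, Bowtie2 2.2.3.0 and SAMtools, and the authors used DESeq2 1.10.1. The read counter and the annotation were not given in the sources used here.

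The authors deposited variance-stabilised log2 values for each library, normalised separately in each table. The authors also deposited a mean signal per gene over the 4 libraries of a table (the mean normalised count), a log2 fold change with its standard error, a test score that is their ratio, and a p-value with its adjusted p-value. No per-library column was left unused (0 unused). The value given to a gene with 0 reads ranged from 5.00 to 6.94 between tables, so low genes are compressed, most at day 2.

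The transformation was inverted to recover the read counts behind the values the authors deposited. Of the recovered low values, 100% lay within 0.02 reads of a whole number, checked up to 100 reads. Totals were 20153362 to 33973608 reads, with 19838 to 21219 genes having a read and at most 2.00% of reads in 1 gene. Levels are recovered reads scaled to library size (RPM).

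Knockdown effects were tested with limma 3.58.1 (R 4.3.3, statmod 1.5.0) on the deposited log2 values, with a trend and robust estimation of the spread. Each of the 10 groups had its own mean, with 10 residual degrees of freedom, and every knockdown contrast was taken within a day. A change of effect is the difference of 2 such contrasts from tables transformed separately, so for low genes it may reflect unequal compression. The average effect was fitted with day as a factor (10 libraries per arm, 14 residual degrees of freedom). That fit counts the libraries of an arm as independent, although they may share 1 selected cell population over the days. Genes with a mean normalised count of at least 10 in at least 1 table were tested, which gave 16497 genes. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Gene lists were tested with camera at a correlation of 0.01, with an estimated correlation, and with fry, where at least 5 members were tested.

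The comparisons, filters, gene lists and naming rule were fixed before the data were examined. The rule named the 8 largest changes per direction among called genes with a level above the median. It also named up to 4 members per list with the smallest adjusted p, and Tcf7l2, Axin2, Lef1, Pparg, Cebpa, Adipoq and Fabp4. At single days and in the time course, the libraries of the groups compared could not overlap for the largest changes. For the average effect, the difference of group means had to keep 1 sign on all days instead, and for changes of effect neither was required. Predicted genes without a name were counted in the rule and left unnamed, and 1 gene the rule named, with a list chosen later that holds it, is not reported here.

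The control time course departs from that design. The design allowed a test only if the tables had been normalised together, and otherwise levels with no test. The tables were normalised separately, and the time course was nevertheless tested with limma voom on recovered counts, scaled over all 20 libraries. This was decided after the data were examined.

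The labels give both hairpins libraries numbered 1 and 2. Deviations of same-numbered libraries from their group means correlated at 0.78, 0.70, 0.55, 0.54 and 0.47 at days 0 to 8. Pairing by number was read from these correlations, since the labels name no shared culture. The main fits, and every call not given with the replicate block, left this pairing out. A fit with the replicate number as a block had 5 residual degrees of freedom. Libraries of a group were checked for being copies of each other and were not, with Spearman correlations of 0.949 to 0.992.

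Alternatives were no filter, a filter at 50 (13606 genes), quantile normalization, median centring, no trend and no robust estimation, the replicate block, a change of at least 1.5-fold, a separate fit per table, and leaving out each library. Fits on recovered counts with and without the block, on libraries of 1 number alone and without late libraries numbered 2, and a test of the Tcf/Lef list without Tcf7l2, were added after the data were seen.

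The scripts were tested on simulated data with 16497 genes. Changes were planted only in genes at or above the median level. Genes of similar level had the same spread in all groups, and same-numbered libraries shared no deviation. In the data the 2 scrambled libraries of day 8 differed more than the 2 knockdown ones (SD across genes of 0.598 and 0.263). The shares recovered may therefore overstate what the data allow. Of 2-fold changes 86.6% were recovered at day 0, 80.6% at day 2, 97.0% at day 8 and 100% for the average effect, and 53.7% for the change of effect at day 8. Of 1.5-fold changes 35.8% were recovered at day 0, 16.4% at day 2 and 37.3% at day 8. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Gene order came from a GRCm38 annotation in which 94.1% of the tested genes were found, and no coordinates are given because the build differs.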

Results

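Gene expression was measured by RNA-seq in 3T3-L1 cells, a mouse preadipocyte line that forms lipid-filled adipocytes after hormonal induction. The cells carried a lentiviral hairpin against Tcf7l2, a transcription factor that acts with beta-catenin downstream of Wnt signals, or a scrambled hairpin. Cultures were sampled at days 0, 2, 4, 6 and 8 of differentiation, with 2 libraries per hairpin and day, which gives 10 groups and 20 libraries. The total per library ranged from 20153362 to 33973608 reads. The design asks which genes depend on Tcf7l2 during adipogenesis. Since the labels name 1 knockdown construct, an effect of the vector or hairpin cannot be told from loss of Tcf7l2 for any gene. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. For each gene 1 spread was shared by all 10 groups, also in the tests of single days. The difference between the 2 scrambled libraries had an SD across genes of 0.598 at day 8 and 0.199 at day 2. Counts of called genes can therefore not be compared between days: fits of 1 table alone gave 0, 264, 111, 52 and 0 at days 0 to 8. Levels are given as reads scaled to library size (RPM), as mean ± SD with n = 2 per group. Unless stated otherwise, differences in this part are knockdown minus scrambled in the deposited variance-stabilised log2 values, with their standard error (SE). These values compress changes, most in low genes, so a difference can be smaller than the ratio of the RPM levels.

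Tcf7l2 (ENSMUSG00000024985.11), the silenced gene, was lower in both knockdown libraries than in both scrambled libraries at each of the 5 days. At day 0 its level was 17.8 ± 6.38 RPM in knockdown cells and 49.3 ± 12.5 in scrambled cells (SD, n = 2). At day 8 the levels were 17.5 ± 2.05 and 53.9 ± 4.74 (SD, n = 2). The knockdown level was 36.1% of the scrambled level at day 0, 39.5% at day 2, 31.7% at day 4, 31.3% at day 6 and 32.5% at day 8. In the deposited log2 values the changes were -1.30, -1.04, -1.43, -1.52 and -1.51, with limma adjusted p of 0.0131, 0.0466, 0.00139, 0.00130 and 0.00117. On recovered reads, which are not compressed, the log2 changes were -1.49, -1.34, -1.66, -1.66 and -1.63. Averaged over the days, Tcf7l2 fell by 1.36 (SE 0.0866, adjusted p = 2.61e-08, 10 libraries per arm). The day 2 call ended in 14 of the 20 fits that left out 1 library, with adjusted p from 0.0506 without scrambled library 1 of day 6 to 0.484 without scrambled library 2 of day 2. The day 0 call ended without scrambled library 2 of that day (adjusted p = 0.177) or without knockdown library 1 (adjusted p = 0.0650). In fits of 1 table alone the change was the same and the calls of days 0, 6 and 8 ended (adjusted p = 0.427, 0.0520 and 0.336), and with no filter on low genes those of days 0 and 2 did (0.0735 and 0.188). Without the 6 libraries numbered 2 of days 4, 6 and 8, the calls of days 0, 2, 4 and 8 ended (-1.30, -1.04, -1.35 and -1.32; adjusted p = 0.0528, 0.117, 0.158 and 0.108). Median centring ended that of day 2 (0.0556).

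**Figure D1:**
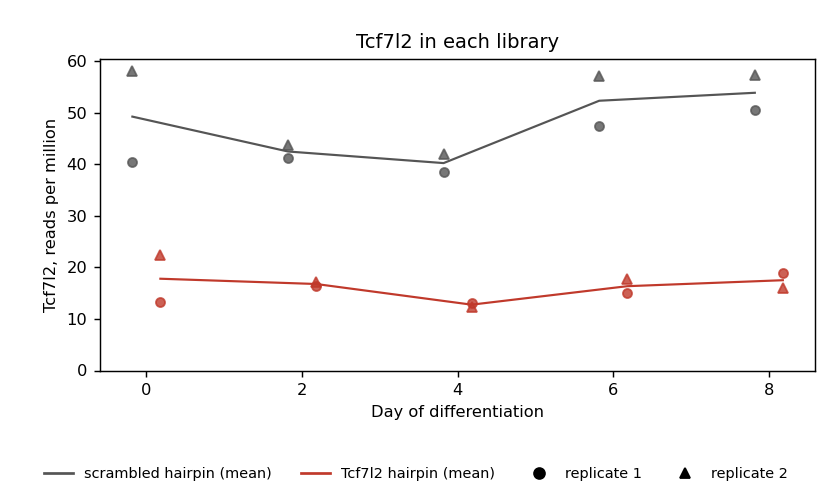
Tcf7l2 level in RPM (vertical axis, starting at 0) against day of differentiation (horizontal axis), with a symbol for each library and a line through the mean of each group. The 10 scrambled libraries lie between 38.5 and 58.1 and the 10 knockdown libraries between 12.4 and 22.3.

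At day 0, before induction, Add3, Fgfr2 and Lgr4 were lower in knockdown cells. Add3, a membrane skeleton gene, changed by -1.60 (SE 0.205, adjusted p = 0.00819). Fgfr2, a fibroblast growth factor receptor, changed by -1.30, and Lgr4, an R-spondin receptor that strengthens Wnt signals, by -1.24. Gpr155, Fbln5, Peli2 and Plekhg3 fell by 0.95, 0.82, 0.77 and 0.72. Hspa4l, a chaperone, and Psmb10, an immunoproteasome subunit, rose by 0.96 and 0.74, and the call of Hspa4l ended on recovered reads (adjusted p = 0.0503). With no filter the calls of Fgfr2, Lgr4, Fbln5, Plekhg3, Hspa4l and Psmb10 ended (adjusted p = 0.0776, 0.0735, 0.0733, 0.149, 0.128 and 0.0523). In a fit of this table alone 0 genes passed, and these 9 genes had adjusted p from 0.303 to 0.361. In all, 37 of 16497 genes passed (24 higher, 13 lower), and 132 with the replicate number as a block. The count was 6 or 3 without scrambled library 1 or 2 of that day, 4 without knockdown library 2, and 67 without either scrambled library of day 8.

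At day 2, Ndn (necdin, an imprinted growth regulator), Lgals3bp (a galectin-binding secreted protein) and Nup107 (a nuclear pore component) rose in knockdown cells. Their changes were 1.49, 1.31 and 1.18. Syt13 rose by 1.63, Lhfpl2 by 1.12 and Lgals9 by 1.40, the last losing its call with the replicate block (adjusted p = 0.0777). Gpr155, Add3, Fbln5 and Peli2, lower at day 0, were lower again, with changes of -1.21, -1.21, -1.18 and -0.68, as was Fgfr2 (SE 0.195, adjusted p = 0.0369). Fam107a fell by 1.43 and Mtap9 by 0.55. With no filter the calls of Lgals9, Fam107a, Add3, Fgfr2 and Mtap9 ended (adjusted p = 0.198, 0.136, 0.118, 0.142 and 0.0735). A fit of this table alone ended those of Lhfpl2, Fam107a and Mtap9 (0.0536, 0.0561 and 0.0578). Without the 6 late libraries numbered 2 those of Lhfpl2, Add3, Peli2 and Mtap9 ended (0.0566, 0.0591, 0.0557 and 0.107). Lgals9 also lost its call under median centring (0.0602) and quantile normalization (0.0523), and Mtap9 under median centring (0.0743). In all, 44 genes passed (31 higher, 13 lower), 128 with the replicate block and 102 on recovered reads. Leaving out any library of that day brought the count to between 7 and 8: 7 without scrambled library 1 or knockdown library 1, and 8 without scrambled library 2 or knockdown library 2.

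At day 4, genes of the interferon response took up most of the leading increases. Oasl2 rose by 4.75, Ifit3 by 4.68, Ifit1 by 4.56 and Isg15 by 3.71, and all 4 calls ended without the 6 libraries numbered 2 of days 4, 6 and 8, which leaves 1 library per arm at this day (4.43, 4.00, 4.10 and 3.35; adjusted p = 0.0909, 0.147, 0.101 and 0.0722). Ifit1 stood at 2.17 ± 0.530 RPM in scrambled cells and 122 ± 39.8 in knockdown cells (SD, n = 2). Gvin1, an interferon-induced GTPase that shares sequence with Gm4070, rose by 4.05, and Ifit genes also share sequence, so single levels in these families are uncertain. Among decreases, Peg10, an imprinted gene, fell by 2.54, Lcn2 (lipocalin 2) by 1.80, Ldhb by 1.78, Fam107a by 1.33, Add3 by 1.32 and Epas1, which encodes a hypoxia-inducible factor, by 1.31. Hipk2 fell by 1.36, with adjusted p = 0.0491 that became 0.0564 with the replicate block and 0.0602 on recovered reads. Without those 6 libraries the calls of Hipk2 (-0.92, adjusted p = 0.472), Peg10 (-1.69, 0.113), Lcn2 (-1.63, 0.101), Add3 (-1.33, 0.127), Fam107a (-1.82, 0.0597) and Gvin1 (3.73, 0.0584) ended as well. Without the 3 scrambled ones of them those of Hipk2 (-0.96, 0.218) and Lcn2 (-1.44, 0.0732) did. In a fit of this table alone the calls of all 7 decreases named here ended (adjusted p from 0.126 to 0.450). With no filter all of them but that of Add3 ended (Peg10 0.188, Lcn2 0.0542, Ldhb 0.128, Fam107a 0.0675, Epas1 0.141 and Hipk2 0.205). In all, 266 genes passed (233 higher, 33 lower), and 512 with the replicate block (335 higher, 177 lower). The count was 126 without scrambled library 2 of that day, 156 without knockdown library 1 and 115 without knockdown library 2.

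At day 6, Hsd11b1, which regenerates active glucocorticoid in adipocytes, fell by 3.07, from 252 ± 76.7 to 27.4 ± 9.69 RPM (SD, n = 2). Slc1a3 (a glutamate transporter), Ces1f (a carboxylesterase), Parm1, Pdzd2 and Col15a1 (a basement membrane collagen) fell by 2.53, 2.49, 2.35, 2.34 and 2.26. Siglec1, a macrophage receptor gene, fell by 2.60, and its call ended on recovered reads (adjusted p = 0.0578). Ifit3, Oasl2, Ifit1, Ifi44, Isg15 and Bst2 rose by 3.78, 3.77, 3.66, 3.52, 3.34 and 3.11. Without the 6 libraries numbered 2 of days 4, 6 and 8 the calls of Ifit3, Oasl2 and Ifit1 ended (3.16, 3.81 and 3.07; adjusted p = 0.129, 0.0571 and 0.102), as did those of Slc1a3 (-2.02, 0.173) and Ces1f (-2.18, 0.135). In a fit of this table alone the calls of Hsd11b1, Slc1a3, Ces1f, Parm1, Col15a1, Siglec1, Ifit3, Ifit1 and Isg15 ended (adjusted p from 0.0504 to 0.174). With no filter those of Hsd11b1, Slc1a3, Ces1f, Pdzd2, Col15a1, Siglec1, Ifit3 and Ifit1 did (0.0833, 0.0703, 0.0787, 0.0600, 0.128, 0.122, 0.0703 and 0.0554). In all, 679 genes passed (442 higher, 237 lower), 2967 with the replicate block (1532 higher, 1435 lower) and 424 on recovered reads. The count was 93 without scrambled library 2 of that day, 96 and 146 without knockdown library 1 or 2, 2330 without scrambled library 1, and 1787 and 1790 without scrambled library 1 or 2 of day 8.

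At day 8, Hsd11b1 fell by 3.40, Lgals12 (a galectin of adipocytes) by 3.27, Pdzd2 by 2.58, Abcd2 (a peroxisomal fatty acid transporter) by 2.55, Slc1a3 by 2.49 and Adipoq, which encodes adiponectin, by 2.47. Adipoq stood at 2180 ± 1865 RPM in scrambled cells and 324 ± 116 in knockdown cells (SD, n = 2). The calls of Lgals12 and Adipoq ended on recovered reads (adjusted p = 0.0892 and 0.0597). Ifit1, Ifit3, Oasl2, Ifi44 and Isg15 rose by 3.51, 3.27, 3.27, 3.06 and 2.82. Without the 6 libraries numbered 2 of days 4, 6 and 8 their changes were 2.07, 1.73, 1.94, 1.83 and 1.57 and all 5 calls ended (adjusted p from 0.221 to 0.527), as they did in a fit of this table alone (0.372 to 0.412), where 0 genes passed and the 6 decreases named here had adjusted p from 0.350 to 0.474. With no filter the calls of Ifit1, Ifit3, Lgals12, Adipoq and Slc1a3 ended (0.0512, 0.0922, 0.111, 0.124 and 0.0601), and without the 3 scrambled ones of those 6 libraries the 5 increases except Ifi44 lost their calls (0.0576 to 0.142). Without those 3 the calls of Adipoq (-1.46, adjusted p = 0.0871) and Slc1a3 (-1.81, 0.0662) ended too, and without all 6 those of Hsd11b1 (-2.63, 0.0541), Pdzd2 (-1.80, 0.0745) and Slc1a3 (-1.98, 0.243). Pparg, the master regulator of adipogenesis, was at 263 ± 221 and 50.1 ± 10.7 RPM (SD, n = 2), a change of -2.05 with adjusted p = 0.0548, and 0.0127 with the replicate block. In all, 948 genes passed (560 higher, 388 lower), 2817 with the replicate block and 511 on recovered reads. The day 8 count was liberal in a simulation with the same spread in all groups: 31 of the unchanged genes were called there, against 2 on recovered reads. It was 3766 without scrambled library 1 of that day, 115 without scrambled library 2, and 295 and 147 without knockdown library 1 or 2.

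Averaged over the 5 days, interferon-response genes were higher and adipocyte genes lower in knockdown than in scrambled cells. Leading increases by the naming rule included Ifit1 (3.29, SE 0.338), Oasl2 (3.19, SE 0.344), Ifit3 (3.17, SE 0.385), Ifi44 (2.91, SE 0.305) and Gvin1 (2.71, SE 0.284). The leading decreases were Slc1a3 (-1.90, SE 0.243), Retn, which encodes resistin (-1.87, SE 0.558), Hsd11b1 (-1.83, SE 0.402), Fabp4, a fatty acid binding protein (-1.79, SE 0.339), Dgat2, an enzyme of triglyceride synthesis (-1.77, SE 0.442), Ces1f (-1.77, SE 0.274), Cidec, a lipid droplet protein (-1.76, SE 0.462), and Anxa8 (-1.70, SE 0.307). Adjusted p of these genes ranged from 5.07e-06 for Ifit1 to 0.0223 for Retn. The call of Retn ended with no filter (adjusted p = 0.0712), and those of Retn, Hsd11b1, Dgat2 and Cidec in libraries numbered 2 alone (0.0781, 0.0809, 0.0519 and 0.0595). That of Hsd11b1 ended in libraries numbered 1 alone as well (0.0581). In all, 4195 genes passed (2023 higher, 2172 lower), and 3462 of them kept 1 sign in the group means of all 5 days. With a change of at least 1.5-fold as well, 900 genes passed (429 higher, 471 lower). With no filter on low genes the count was 2696, in the 10 libraries numbered 2 alone it was 722, and without both libraries numbered 2 of days 4, 6 and 8 it was 2794.

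Among the mature adipocyte markers, 18 of the 22 tested fell on average and none rose (21 fell adjusted over the list alone), with a median change of -1.35. Fabp4 and Adipoq fell by 1.79 and 1.37, Plin4 by 1.46, Fabp5 by 1.34 and Cd36, a fatty acid transporter, by 1.69. The list passed camera with a preset correlation (adjusted p = 5.95e-09) and not with an estimated correlation between genes (adjusted p = 0.450). The 2 scrambled libraries of day 8 lay far apart: Adipoq was at 3499 RPM in library 2 and 862 in library 1, and Fabp4 at 4080 and 579.

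**Figure D2:**
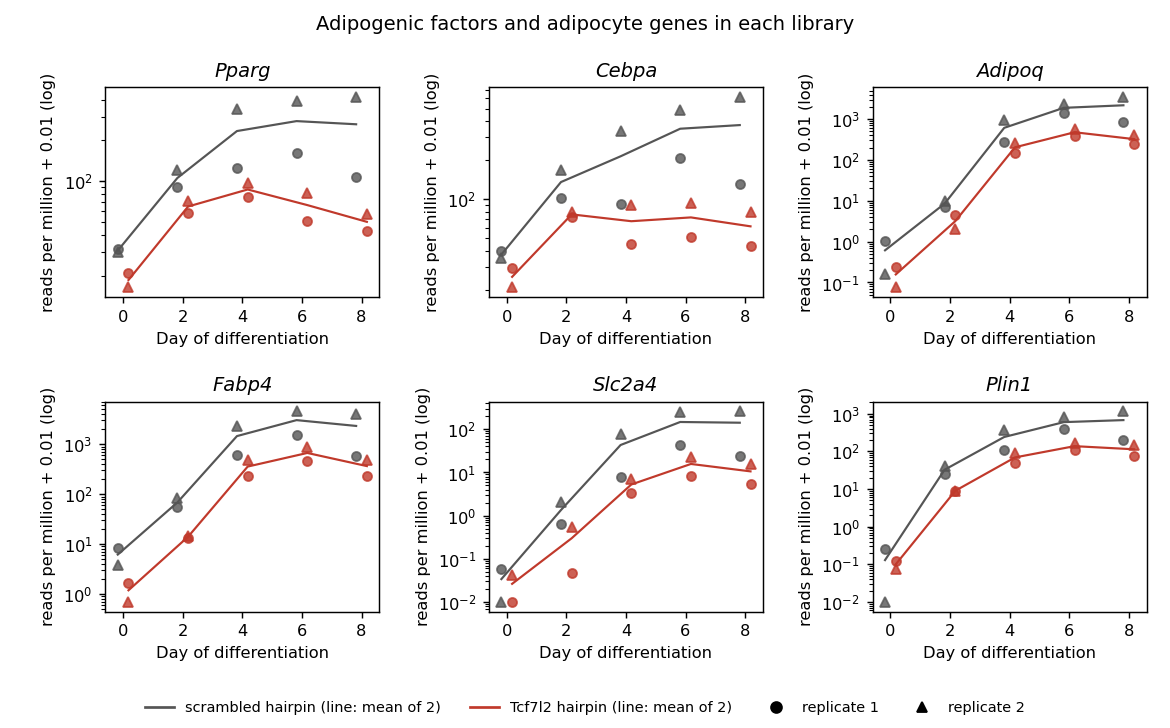
Levels of 6 adipocyte genes in each library, in RPM plus 0.01 on a log axis, against day of differentiation, with a line through the mean of each group of 2. At day 8, Pparg was at 107 and 420 in the scrambled libraries and at 42.5 and 57.6 in the knockdown libraries.

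Of the adipogenic transcription factors, 12 of 19 were lower (15 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.53e-05; adjusted p = 0.450 with an estimated correlation). Pparg fell by 1.29 (SE 0.269, adjusted p = 0.00276) and Cebpa by 1.41 (SE 0.326, adjusted p = 0.00546), and Rxra, Ebf2, Stat5a and Zfp423 by 0.45, 0.79, 0.48 and 0.59. Of the preadipocyte markers and inhibitors of adipogenesis, Gata3, Ly6a and Cd34 rose by 0.46, 1.15 and 0.26 and Pdgfra fell by 0.48, while 14 of 18 did not pass and the list did not (camera adjusted p = 0.154). Of the brown and beige adipocyte markers, Tmem26, Ebf2 and Ppargc1a fell by 0.64, 0.79 and 0.61 and Dio2, the thyroid hormone activating deiodinase, rose by 0.62. That list had 4 of 8 lower and 1 higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.0116; adjusted p = 0.450 with an estimated correlation). Without the 3 late scrambled libraries numbered 2 its call ended (adjusted p = 0.0711) and its median moved from -0.47 to -0.14.

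Of the lipid and energy metabolism genes that were called, most were lower. In lipolysis, 8 of 11 fell (9 adjusted over the list alone), among them Plin1 (-1.39), Lipe (-1.36), Pnpla2 (-1.27) and Adrb1 (-0.37). In fatty acid and triglyceride synthesis, 10 of 20 fell (13 adjusted over the list alone), with Dgat2, Lpin1 and Acacb at -1.77, -1.24 and -0.63, and the elongase Elovl6 rose by 0.47. In cholesterol synthesis and uptake, 10 of 21 fell (11 adjusted over the list alone), including Cyp51 (-1.06), Acat2 (-0.91), Insig1 (-1.40) and Lss (-0.57). In fatty acid oxidation, 11 of 17 fell and 1 rose (13 and 1 adjusted over the list alone), with Cpt2, Acads, Etfa and Hadha at -0.91, -0.88, -0.68 and -0.74. In oxidative phosphorylation, 13 of 19 fell (18 adjusted over the list alone), with Cycs at -1.01, Ndufs1 at -0.77, Ndufa9 at -0.61 and Cox6c at -0.41. In insulin signalling and glucose uptake, 10 of 19 fell and 2 rose (12 and 2 adjusted over the list alone): Tbc1d4, Irs1 and Irs2 fell by 0.72, 0.63 and 0.59, and the hexokinase Hk1 rose by 0.35. Camera adjusted p with the preset correlation ran from 3.50e-06 for oxidative phosphorylation to 0.00392 for insulin signalling. With an estimated correlation the adjusted p were 0.454 (lipolysis, oxidative phosphorylation), 0.463 (fatty acid synthesis), 0.455 (cholesterol, fatty acid oxidation) and 0.450 (insulin signalling).

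The interferon response list rose as a whole: 22 of 22 tested members were higher (22 adjusted over the list alone), with a median change of 2.15. Mx1 rose by 2.98, Bst2 by 2.42 and Rtp4 by 2.18. Camera adjusted p was 2.09e-25 with the preset correlation, and adjusted p = 0.263 with an estimated correlation. By day, 21 members were called higher at day 4, 21 at day 6 and 21 at day 8, and 0 at day 0 and at day 2. The median changes at days 0 and 2 were 1.70 and 1.11, and the transformed values compress low genes, most at day 2; on recovered reads the medians were 2.38 and 3.33. Of the macrophage and leukocyte markers, Cd14 rose by 0.48 and 4 of 5 did not pass (camera adjusted p = 0.188); Itgam, Lyz2 and Csf1r had values of 0.18, 0.24 and 0.03.

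**Figure D3:**
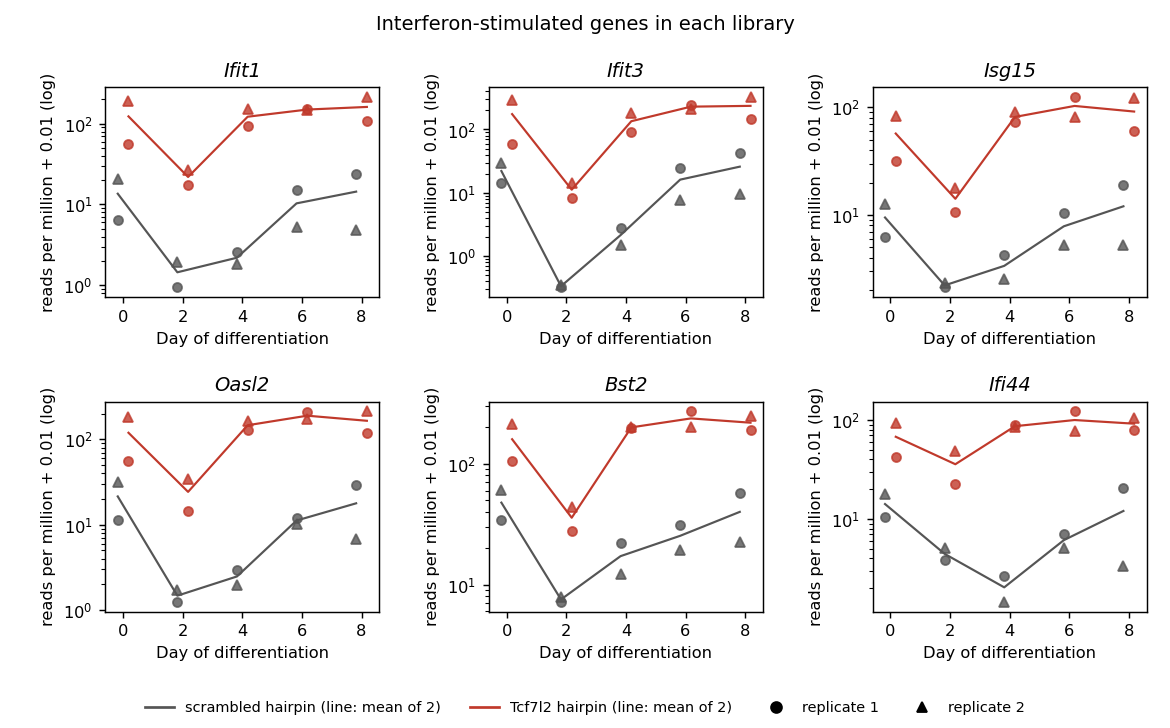
Levels of 6 interferon-stimulated genes in each library, in RPM plus 0.01 on a log axis, against day of differentiation, with a line through the mean of each group of 2. At day 4, Isg15 was at 4.20 and 2.52 in the scrambled libraries and at 72.9 and 90.2 in the knockdown libraries.

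Of the inflammatory and acute phase genes, 6 of 16 rose and 3 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.0862). The chemokine genes Ccl2 and Ccl7 rose by 1.98 and 1.95, Ptgs2 by 0.72 and the adhesion gene Vcam1 by 0.78. Of the contractile, SRF and YAP targets, 11 of 17 were higher and none lower (13 higher adjusted over the list alone; camera adjusted p = 4.74e-06; adjusted p = 0.450 with an estimated correlation). Tpm1 (tropomyosin) rose by 0.81, Cnn2 by 0.71, Cyr61 by 0.68 and Ankrd1 by 0.60. Extracellular matrix genes went both ways, 11 of 35 higher and 4 lower (13 and 4 adjusted over the list alone; camera adjusted p = 0.134). Thbs1 and Tnc rose by 1.36 and 1.26, and Col15a1 and Lum fell by 1.65 and 0.97.

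Of the Tcf/Lef factors and beta-catenin partners, 5 of 15 fell and 1 rose (6 and 1 adjusted over the list alone). Besides Tcf7l2 itself, Lef1 fell by 0.68 (SE 0.112, adjusted p = 0.00044), Tcf7l1 by 0.46 and Bcl9l by 0.24. The list holds Tcf7l2 itself, whose fall is part of the design (camera adjusted p = 0.0312; adjusted p = 0.263 with an estimated correlation). With Tcf7l2 left out, a test added after the result was seen, the other 14 members did not pass (adjusted p = 0.140, median -0.03; adjusted p = 0.450 with an estimated correlation). The call of the whole list ended under quantile normalization (adjusted p = 0.0632), without scrambled library 2 of day 0 (0.0555), without scrambled library 1 of day 4 (0.0544) and in the libraries numbered 2 alone (0.270). Of the 7 tested Wnt/beta-catenin targets and feedback genes, Wisp2 rose by 0.58 and 6 did not pass (camera adjusted p = 0.304). The call of Wisp2 ended with no filter (adjusted p = 0.0515), without the 3 or 6 late libraries numbered 2 (0.0675 and 0.130) and in libraries numbered 1 or 2 alone (0.188 and 0.0766). The others did not pass, with Wisp1, Kremen1 and Ccnd1 at 0.28, 0.10 and 0.33. Axin2, a common readout of beta-catenin activity, was below the expression filter, with group means from 0 to 0.284 RPM. Of the Wnt ligands, receptors and secreted antagonists, Ror2 rose by 0.42 and Fzd4, Lrp6 and Wnt10a fell by 0.63, 0.44 and 0.23, 4 of 20 going each way (4 higher and 5 lower adjusted over the list alone; camera adjusted p = 0.634).

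The other lists moved in few members. Tgfb2, Id1 and Tgfbr1 fell by 0.86, 0.71 and 0.26 and Tgfbr2 rose by 0.40 in the TGF-beta and BMP pathway (13 of 17 not past; camera adjusted p = 0.634). Ccne1, Ccne2 and Rrm2 fell by 0.59, 0.39 and 0.43 among 25 cell cycle genes (adjusted p = 0.634), and no replication-dependent histone of 15 passed (0.852). Eda2r and Plk2 rose by 0.92 and 0.71 among 13 p53 targets (0.135). Chac1 rose by 0.68 and Dnajb9 and Pdia4 fell by 0.66 and 0.63 among 15 genes of the unfolded protein and integrated stress response (0.751). Phex and Sp7 fell by 0.38 and 0.20 among 7 osteoblast markers (0.634), and Col11a1 rose by 0.57 and Sox5 fell by 0.56 among 6 chondrocyte markers (0.420). Too few members were measured to test 4 muscle, 3 endothelial and 4 epithelial markers, of which Krt14 fell by 0.26, and 0 mitochondrially encoded genes were present. Adjusted over the list alone, the counts were 1 higher and 3 lower for the TGF-beta and BMP pathway, 3 lower for the cell cycle, 2 higher for p53, 1 and 2 for the stress response and for osteoblast markers, and 1 and 1 for chondrocyte markers. For osteoblast markers the median was -0.04 and the mean 0.02. Some calls of list members named above ended in other settings. With no filter they were those of Tgfbr1, Ccne2, Sp7, Cd34 and Krt14 (adjusted p = 0.0832, 0.0612, 0.119, 0.0524 and 0.125), Rrm2, Pdia4, Chac1 and Col11a1 (0.0834, 0.0504, 0.0822 and 0.0526), and Pdgfra, Lss and Irs2 (0.0627, 0.0522 and 0.0578). Without the 3 late scrambled libraries they were those of Tgfbr1, Ccne2, Sp7, Cd34 and Krt14 (0.172, 0.107, 0.280, 0.0767 and 0.0594). Without the 6 late libraries the same 5 calls ended (0.405, 0.188, 0.306, 0.220 and 0.0545), and those of Cox6c, Irs2, Id1 and Col11a1 (0.112, 0.0603, 0.0782 and 0.108). Libraries numbered 1 alone ended those of Cd34, Tgfbr1, Ccne2 and Sp7 (0.125, 0.312, 0.0908 and 0.357), Lipe, Pnpla2, Acads and Cycs (0.0507, 0.0544, 0.0652 and 0.0506), and Dio2, Ppargc1a and Vcam1 (0.114, 0.0854 and 0.0618). Without trend and robust estimation those of Sp7 and Krt14 ended (0.0525 and 0.0501). In libraries numbered 2 alone 54 calls of named genes ended, among them those of Adipoq, Fabp5, Plin1 and Pnpla2 (0.0619, 0.0533, 0.0642 and 0.0786). Of the 25 lists tested 12 passed, and 0 with an estimated correlation. The design only counted list members at single days, so tests of the 25 lists at each of the 5 days were not planned. With an estimated correlation 2 of these passed, both at day 2. The inflammatory and acute phase list had 14 of 16 members higher, 1 of them called (median 0.50; camera adjusted p = 8.72e-10; adjusted p = 0.000932 with an estimated correlation). The Tcf/Lef list, which holds Tcf7l2, its only called member there, had a median of -0.10 (camera adjusted p = 0.000493; adjusted p = 0.0255 with an estimated correlation).

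**Figure D4:**
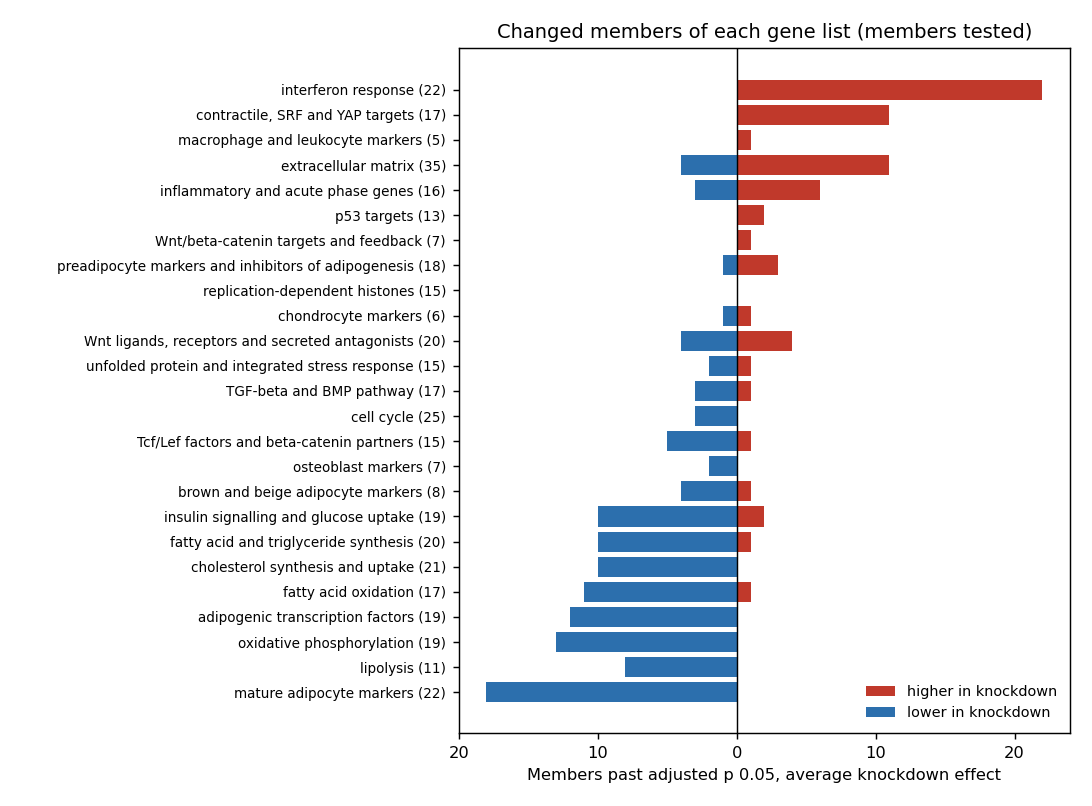
Number of members of each list past adjusted p 0.05 for the average knockdown effect, higher to the right and lower to the left of 0, with the number tested in brackets. The interferon response has 22 of 22 higher and the mature adipocyte markers 18 of 22 lower.

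Whether the knockdown effect differed between days was tested for each gene against day 0. For day 2, 3 genes passed: Dio2 (1.34), Krt9 (-1.17) and Ppp1r1b (-1.47), which were named because the count is small. With the replicate block, on recovered reads, with the stricter filter or without the 3 or 6 late libraries, 0 passed, and with no filter 23 did. For days 4, 6 and 8 limma called 0, 0 and 0 genes, with 480, 1134 and 1128 at an unadjusted p under 0.05 (521, 938 and 773 on recovered reads, where 0 passed as well). With the replicate block 1 gene, Lcn2, passed for day 6, at -2.52. Without scrambled library 1 of day 8, 690 genes passed for day 8, and without scrambled library 2 of day 8, 2 genes. With no filter 20, 26 and 20 genes passed for days 4, 6 and 8. Without the 3 late scrambled libraries 11 and 4 passed for days 6 and 8, and without the 6 late libraries 57 and 16, so whether the effect in single genes changed at the late days depends on the setting and is left open.

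In the scrambled arm, differentiation raised adipocyte genes over the time course. From day 0 to day 2, Glul rose by 5.12, Adamts15 by 4.51, Acsl1, an acyl-CoA synthetase, by 4.37, Pnpla2 by 4.30, the glucocorticoid target Fkbp5 by 4.01 and C3 by 4.01, while Pltp, Acta2 (smooth muscle actin) and Pdpn fell by 3.72, 3.27 and 3.22. From day 0 to day 8, Adipoq rose by 12.15, Cd36 by 11.57, Gpd1 by 10.67 and Fabp4 by 8.12, and Grem1, a BMP antagonist, fell by 3.23, with its call ended without the 3 or 6 late libraries (-1.96 and -1.97; adjusted p = 0.0883 and 0.109). These fits used recovered reads, because the 5 tables were normalised separately and their values cannot be compared across days. For this case the design fixed before the data were examined gave no test, so the time course tests were added afterwards. Counts against day 0 were 4067 at day 2, 2288 at day 4, 2981 at day 6 and 1727 at day 8, and 6478, 5686, 6163 and 4986 with the replicate block. Single libraries decided them: without scrambled library 2 of the later day they were 1751, 457, 152 and 215, without scrambled library 2 of day 0 2339, 809, 1023 and 447, and without scrambled library 1 of day 0 750, 304 and 255 at days 4, 6 and 8. The count was 2698 at day 2 without scrambled library 1 of day 2, 4701 at day 6 without library 1 of day 6, and 4341 at day 8 without library 1 of day 8.

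By list, the mature adipocyte markers had a median change of 8.92 at day 8, with 17 of 22 higher (camera adjusted p = 1.11e-17; adjusted p = 0.311 with an estimated correlation). Cholesterol synthesis had 19 of 21 higher at day 8 (median 2.02; camera adjusted p = 6.05e-16; adjusted p = 0.311 with an estimated correlation). Contractile, SRF and YAP targets had 10 of 17 lower at day 2 (median -1.12; camera adjusted p = 0.000392; adjusted p = 0.671 with an estimated correlation). Interferon response genes had 9 of 22 lower at day 2 (median -2.61; camera adjusted p = 5.91e-05; adjusted p = 0.673 with an estimated correlation). In the knockdown arm the same fit called 2535, 510, 96 and 111 genes at days 2, 4, 6 and 8. That the 2 arms differ in these counts was not tested beyond the tests of single genes above.

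In the authors' deposited table, Tcf7l2 had log2 changes of -0.96, -1.18, -1.51, -1.55 and -1.50 at days 0 to 8. These fold changes are another measure than the differences given above, and their sizes cannot be set side by side. At day 0 the change of Tcf7l2 on recovered reads was -1.49. In the authors' deposited table Pparg was called lower at days 2, 6 and 8 (-0.62, -1.70 and -1.81), Cebpa at the same days (-0.70, -1.85 and -1.85) and Lef1 at days 2, 4 and 6 (-0.62, -0.89 and -1.13). In the authors' deposited table Fabp4 was called at days 0, 2, 6 and 8 (-0.90, -1.91, -1.70 and -1.74) and Adipoq at days 2, 6 and 8 (-0.90, -1.75 and -2.04). The numbers of genes called in the authors' deposited table were 266, 742, 407, 999 and 591, which include 34 of 37, 43 of 44, 233 of 266, 442 of 679 and 384 of 948 genes called here.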

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

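In this part only the 100 splits were predicted before their results were seen, and the other tests of the interferon and adipocyte patterns were chosen after the results were seen. Groups of 2 are too small for an outlier rule.

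A difference of the knockdown effect between day 2 and day 0 was called for Dio2 (1.34), Krt9 (-1.17) and Ppp1r1b (-1.47), each with adjusted p = 0.0196. These genes had hardly any reads at day 0 (Dio2 0.0393 and 0.101 RPM), and on recovered counts the changes were 2.21, -3.51 and -4.33 and the adjusted p of all 3 was 1.00. Dio2 was at 14.3 ± 4.54 RPM in knockdown cells and 1.62 ± 0.0726 in scrambled cells at day 2 (SD, n = 2). Krt9 was at 0.236 ± 0.0754 and 6.50 ± 1.04, and Ppp1r1b at 0.400 ± 0.0999 and 9.03 ± 2.56 (SD, n = 2).

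On recovered counts, a test of the difference between day 8 and day 0 also called 16 of 25 lists. Lower at day 8 than at day 0, as the median change of the effect, were adipogenic transcription factors (-0.52, adjusted p = 0.0168), mature adipocyte markers (-1.82, 0.000549), fatty acid and triglyceride synthesis (-1.24, 2.48e-08), cholesterol synthesis (-1.20, 5.83e-15), lipolysis (-2.14, 0.000907), fatty acid oxidation (-1.06, 4.08e-07), oxidative phosphorylation (-0.89, 2.48e-08), chondrocyte markers (-0.43, 0.0482) and histones (-0.69, 0.00137). Higher were Wnt ligands and receptors (0.40, 0.0168), preadipocyte markers (0.40, 0.00446), extracellular matrix (0.56, 0.00446), contractile targets (1.01, 1.18e-08), the cell cycle (0.66, 0.00365), macrophage and leukocyte markers (0.58, 0.0168) and the interferon response (0.65, 0.0143, and 0.0724 with the replicate block). With an estimated correlation all 16 calls were lost, with adjusted p from 0.292 to 0.589. For days 2, 4 and 6 against day 0, camera with the preset correlation called 6, 11 and 14 of 25 lists on recovered counts. With an estimated correlation 1, 0 and 0 passed. The 1 was the inflammatory and acute phase list at day 2 (median 1.19, camera adjusted p = 2.61e-06, and 0.00594 with an estimated correlation). Of its 16 members, 0 were called for this difference.

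Interferon genes were higher in knockdown cultures. Leukocytes as the main source of these transcripts are argued against by the 5 tested of their 11 listed markers. The highest change among them on recovered counts was 0.73, below the lower quartile of 2.24 for the interferon list. The marker score differed by -0.23 at day 0 and by 0.39, 0.32, 0.39 and 0.54 at days 2 to 8 (SE 0.228). A small share of leukocytes is not decided, since its markers would change little. The marker test was moved from the deposited values, where the highest was 0.48, to recovered counts after the first result was seen, with the same outcome. Less advanced differentiation is argued against by the interferon score, which already differed by 2.32 at day 0 (SE 0.624, n = 2). An effect of the vector or hairpin rather than loss of Tcf7l2 cannot be told apart, since the labels of these libraries name 1 knockdown construct.

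Adipocyte genes were lower in knockdown cultures. The lower adipocyte score, taken on recovered counts, was not confined to libraries numbered 2. Those numbered 1 differed by a mean of -1.39 over days 4, 6 and 8, and those numbered 2 by -2.52. By day, those numbered 1 differed by -0.98, -1.82 and -1.36. They already differed by -1.02 at day 0, before induction, and by -0.90 at day 2, so part of their later difference may not arise in differentiation. Those numbered 2 differed by -0.25 at day 0 and -1.49 at day 2. At day 0 the scrambled libraries themselves scored 0.71 and -0.44. The SE of the mean of -1.39, 0.243, is over days with 1 library per arm, so it does not measure the spread between libraries. The difference at a single day had an SE of 0.961 (n = 2 per group). Scaling of the libraries is argued against by a median of -1.33 under quantile normalization. A smaller share of adipocytes with unchanged expression was tested as 1 common change of 19 genes at day 8. The changes ran from -1.82 for Lpl to -4.61 for Retn. Cochran's Q was 46.6 (n = 19 genes, p = 0.000245 from the chi-square distribution). It was taken on limma changes and standard errors from recovered counts with the replicate block. That test treats genes as independent, which genes of the same libraries are not. It cannot decide on a smaller share, because genes also expressed by other cells of the culture would then fall less than the rest. An effect of the vector or hairpin cannot be told from loss of Tcf7l2 here either, since the labels name 1 knockdown construct.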

How the results depend on the processing

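Settings on recovered counts, on libraries of 1 number, without late libraries and without Tcf7l2 in its own list were chosen after the data were seen, and the late libraries were picked because scrambled libraries numbered 2 had higher adipocyte gene levels. The control time course was itself tested against the fixed design, which gave no test for tables normalised separately. Where a setting changed a result, the cause was not tested, except that fits without libraries have fewer samples, and a library left alone in its group is assumed to vary like the other groups. With 2 libraries per group, changes of 1.5-fold on single days were mostly out of reach, and low genes are compressed at day 2. Single results were followed over the settings for 265 results of named genes and for 25 lists, and not for the other called genes. Among those followed, direction was kept by every called gene and list. Of the results for single genes 7406 were the same, 655 weaker, 42 stronger and 26 reversed, and of those for lists 765, 18, 15 and 24. Named genes lost 59 calls with no filter, 54 in libraries numbered 2 alone, 50 in fits within a table, 49 without the 6 late libraries and 18 without the 3 late scrambled ones. Of the named genes called on average, 93 of 98 kept their call in all 20 fits without 1 library, against 0 of 11 at day 0, 2 of 16 at day 2, 6 of 16 at day 4, 1 of 16 at day 6 and 0 of 16 at day 8.

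With no filter the knockdown counts were 18 at day 0, 248 at day 6, 398 at day 8 and 2696 on average, the changes of effect 23, 20, 26 and 20 at days 2, 4, 6 and 8, and Tcf7l2 was at -1.30 (adjusted p = 0.0735) at day 0 and -1.04 (0.188) at day 2. The stricter filter left 0 genes for the change of effect at day 2. Median centring gave Tcf7l2 -1.03 (0.0556) at day 2. A change of at least 1.5-fold left 900 genes on average. With an estimated correlation 0 lists passed, against 16 by fry.

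With the replicate block the knockdown counts were 132, 128, 512, 2967 and 2817 at days 0 to 8, the changes of effect 0 at day 2 and 1 at day 6, and the time course 6478, 5686, 6163 and 4986. Of the named genes the block ended the calls of Lgals9 at day 2 and Hipk2 at day 4, and brought E2f1, Sesn2, Trib3, Spp1, Alpl, Ttn and Des past the threshold on average. At single days it also brought Pparg and Cebpa (days 6 and 8), Adipoq (day 6) and Fabp4 (days 4, 6 and 8) past the threshold. For the change of effect it ended the calls of Dio2, Krt9 and Ppp1r1b at day 2 and of the interferon list at day 8 (0.0724), and added Lcn2 at day 6 and the insulin signalling list at day 8 (0.0419). It changed no call of the other named genes in the comparisons that named them, nor of a list for the average effect. The day 8 time course had 914 genes higher and 813 lower, against 854 and 1140 under quantile normalization and 892 and 1208 under median centring.

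Fits within each table gave 0, 264, 111, 52 and 0 genes at days 0 to 8, and Tcf7l2 -1.30 (0.427) at day 0, -1.52 (0.0520) at day 6 and -1.51 (0.336) at day 8. Recovered counts gave 102 at day 2, 424 at day 6, 511 at day 8 and 0 for the change at day 2. Recovered counts with the replicate block gave 166, 339, 672, 3216 and 2680, 6410 on average, and 0 for the change at day 2. Libraries numbered 2 alone gave 722 on average.

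Without the 3 late scrambled libraries numbered 2 the counts were 263 at day 0, 194 at day 2 and 495 at day 8, the changes of effect 0, 11 and 4 at days 2, 6 and 8, and the time course 1901 and 894 at days 6 and 8. Without all 6 late libraries numbered 2 they were 132, 86, 54 and 243 at days 0, 2, 4 and 8 and 2794 on average, the changes 0, 57 and 16 at days 2, 6 and 8, and the time course 1132, 1204 and 581. Tcf7l2 was then at -1.30 (0.0528), -1.04 (0.117), -1.35 (0.158) and -1.32 (0.108) at days 0, 2, 4 and 8.

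No reversed result was called in the main analysis or in the setting that reversed it. In other settings lists gained calls: cell cycle (adjusted p = 0.0483) and preadipocyte markers (0.0239) in libraries numbered 2; stress response (0.00186), histones (0.00215), p53 targets (0.0199) and inflammatory genes (0.0457) without the 3 late libraries; the same 4 without the 6 late libraries (0.00118, 0.0113, 0.0328 and 0.00809); stress response (0.00157) and inflammatory genes (0.0192) in libraries numbered 1; inflammatory genes with no filter (0.0430). The extracellular matrix list gained one without scrambled library 2 (0.0133) or knockdown library 1 (0.0422) of day 0. Recovered counts with the block: histones -0.011. Without the 3 late libraries: Kremen1 -0.0097, Ccnd1 -0.088, Myl1 0.071, Krt19 0.071, Esrp1 0.095, Krt18 0.195, Hist1h2ae 0.0074, Hist1h2ab 0.0097, cell cycle -0.096. Without the 6 late libraries: Kremen1 -0.0087, Ccnd1 -0.165, Myl1 0.017, Tnnt3 -0.026, Csf1r -0.043, Krt19 0.081, Esrp1 0.046, Krt18 0.111, preadipocyte list -0.067, cell cycle -0.126. Libraries numbered 1: Ccnd1 -0.135, Tnnt3 -0.012, Csf1r -0.048, Krt19 0.135, Esrp1 0.038, Krt18 0.129, preadipocyte list -0.026, cell cycle -0.109. Libraries numbered 2: stress response -0.136, histones -0.097.

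Leaving out 1 library gave counts of 3 to 67, 7 to 61, 115 to 378, 93 to 2330 and 115 to 3766 at days 0 to 8, 3037 to 4626 on average, 0 to 3, 0 to 1, 0 to 1 and 0 to 690 for the changes of effect, 1751 to 4611, 457 to 3260, 152 to 4701 and 215 to 4341 for the time course, and 11 to 13 lists. Tcf7l2 ranged from -1.60 to -0.99, -1.08 to -1.002, -1.48 to -1.38, -1.64 to -1.40 and -1.61 to -1.41 at days 0 to 8 and from -1.41 to -1.32 on average. Uncalled results that changed direction in such a fit ranged from -0.0038 to 0.062 (Tnnt3), -0.0031 to 0.079 (Csf1r), -0.23 to 0.0095 (Krt18), 0.0020 to 0.16 (cell cycle list), -0.012 to 0.172 (stress response list) and -0.031 to 0.115 (histone list).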

Other observations

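In this part the antigen presentation list, the delay test and the chromosome and level tests of Yeats4 and Nup107 were chosen after the results were seen, while the splits and the test of those 2 genes' change in scrambled cells were written before.

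Genes of antigen processing and presentation rose, 11 of 13 tested, with a median change of 0.83. B2m rose by 1.00, H2-D1 by 1.15, H2-K1 by 1.12, Psmb8 by 1.09, Tap1 by 1.25 and Cd74 by 1.48. H2 genes share sequence, so their single levels are uncertain. Camera adjusted p was 2.79e-14, and adjusted p = 0.00284 with an estimated correlation. These were adjusted over the lists chosen later alone, so they cannot be set beside those of the 25 fixed lists. The list also holds Psmb10, already named at day 0, and was taken from the data that it tests, so it is not independent evidence.

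The 20 libraries were regrouped within days in 100 splits, the real one included. As many genes as in the real grouping (4195) were called in 1 of 100, the real one, and the highest other split called 0. As many lists as in the real grouping (12) were called in 45 of 100, with up to 17 in other splits. The number of called lists is therefore not separable from what random regrouping gives, whereas the number of called genes is. The splits regroup libraries day by day, so they cannot tell the hairpin from any other lasting difference between the 2 arms. Libraries of an arm may share 1 selected cell population over the days. The mean change of each list was compared with the splits as well, after the results were seen and with no adjustment over lists. A mean as large was found in 1 of 100, the real one, for 10 of the 12 called lists, in 2 for fatty acid synthesis (-0.67, highest other 0.67) and in 3 for cholesterol synthesis (-0.52, highest other 0.58). Most margins of the 10 were small: oxidative phosphorylation -0.59 against 0.58, brown markers -0.38 against 0.37, lipolysis 0.97 in the highest other split and little more in the real one, insulin signalling -0.43 against 0.40, fatty acid oxidation -0.54 against 0.51, contractile targets 0.41 against 0.36, adipogenic factors -0.50 against 0.44, mature adipocyte markers -1.29 against 1.16, and the Tcf/Lef list, which holds Tcf7l2, -0.18 against 0.13. The interferon list had 2.18 against 1.62. The p53 and inflammatory lists, which were not called, had a mean as large in 1 of 100 too.

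Yeats4 and Nup107, near neighbours on a chromosome, were picked after their values were seen. Yeats4 rose by 1.04 on average (adjusted p = 2.67e-06) and Nup107 by 1.38 (1.03e-06). Extra copies of the whole segment were tested first: the 6 tested genes between them had a median change of 0.013 (median absolute deviation 0.233). Of the 6, Lyz1, Lyz2 and Cpm were low (mean deposited values of 6.88, 7.68 and 7.88), where changes are compressed. Mdm2 and Slc35e3 were at 3077 and 1700 RPM in scrambled cells at day 8, and such high levels may hide a small gain. They changed by 0.03 and -0.20 on average, and the remaining gene, Cpsf6, rose by 0.43 (limma adjusted p = 0.000936). The 0.013 is therefore weak evidence and does not decide on extra copies. A test of well expressed neighbours was then chosen after that result and the neighbours' values were known, and is not independent evidence. The median of 7 neighbours, 0.24, lay at percentile 98.6 of 7953 runs, and 4 of them were called higher and 1 lower on average. Less advanced differentiation was left undecided by the planned test alone, with changes over days 0 to 8 in scrambled cells of -0.57 (SE 0.161) for Nup107 and -0.33 (SE 0.151) for Yeats4. An earlier stage seen in scrambled cells is argued against by the levels: the lowest knockdown library of day 8 lay above the highest scrambled library of any day by 0.65 for Yeats4 and 1.13 for Nup107, with a largest SD within a group of 0.247. These levels compare days on recovered counts, since the tables were normalised separately.

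A delay of the whole differentiation programme predicts a negative correlation of the day 8 effect with the scrambled change from day 0 to day 4. Across 16497 genes r was -0.51 (rho -0.43), which is consistent with a delay, but lower adipocyte expression for any other reason would give it too. Genes are not independent, and no p-value is given.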
